A study of Mus musculus with 6 samples.

How the data were processed

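The series holds 6 arrays of 2 colours from 3 independent experiments on cultured mouse FDB fibres, each experiment with 2 arrays of opposite dye orientation. Per the labels' protocols, total RNA came from over 100 single fibres, was amplified, and was coupled to Cy3 or Cy5. Groups, experiment numbers and dyes were taken from the labels. The 2 arrays of an experiment were taken as the same RNA extracts and counted as 1 replicate.

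Per the file headers, the deposited scanner files hold the intensity of each spot and of its local background as pixel mean, median and SD, from image quantification software of version 5.5, with 144 spots in 9 by 16 positions and 1 subgrid, not background-subtracted. They name no gene for any spot. The deposited value table holds a linear ratio per spot, 132 probes in 22 sets of 6. Its scaling, centring and background correction are not given in the sources used here, and neither is the rule for empty cells, of which a column had 30 to 44. Its column medians were 0.974, 1.036, 1.074, 0.938, 0.978 and 1.264. The direction of each column was read from the sample title, and for experiment 1 it stays open. The labels say that the mean over the spots of a gene was used. Of the probes, 120 had 1 gene symbol, 0 had several and 12 had none. Through gene numbers, 19 of the 20 named genes were found in a mouse RefSeq gene table, used for names only. The exception, CAMTA1, carries a human gene number. Its 6 values of exactly 1 on 1 array were left out as filler.

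The design, the gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. As fixed, scanner intensities were corrected with limma's normexp (offset 50), normalized by loess within each array, and averaged over the 6 spots of a set. They were then turned to stimulated over control by the labelled dyes and averaged over the dye swap. The 3 resulting values per set were tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg, adjusted p under 0.05). That fit is the planned result. Use of the value table in place of the scanner files was fixed as a second way to run the test. It is described at length because it is the only source that names genes, and this choice of emphasis was made after seeing that it gave 7 calls and the planned fit 0. For the table, log2 ratios were averaged over the spots of a gene where at least 3 had a value, and over the dye swap, and 15 probe sets with values in all 3 experiments were tested in the same way. The minimum of 3 spots was also chosen after seeing the table.

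Genes were named for scanner spots only by a match to the value table. The layout gave 24 sets of 6 spots, each of 2 triples. Of the 48 triples, 41 were nearest in brightness to their partner. Sets were matched to probe sets from the ratios of experiments 2 and 3, and a match was accepted at a mean residual of 0.12 log2 or less with the next best set at least 2 times worse. In experiment 2 this used the files of the other array of the swap. Several ways of pairing columns with files were tried before this one. Accepted were 10 sets, 8 with a gene name. On simulated data for 22 probe sets, 100% of accepted matches were right and 14.8 were accepted on average over 20 repeats. The simulated ratios were the scanner ratios themselves with little added noise, each column paired with its own array. They are therefore easier to match than the real table, and the 100% does not measure how many real matches are right. Because the correlations of experiments 2 and 3 over sets chosen for a small residual in those experiments are fixed by the choice, the match was repeated from experiment 2 alone and from experiment 3 alone and read in the other experiments. This was added after the data were seen. The scanner files and the table conflict in experiment 1. The planned scanner fit and its alternatives, and the value table at its reported settings, were therefore also run with that experiment turned. Both sources were also run with it left out. List shifts were turned only at the reported settings.

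Named in the text were all genes past the threshold, all measured members of the slow and fast contractile lists, and from other lists of at least 2 measured members the 3 with the smallest p. Where fewer than 6 pass, the rule names the 10 with the smallest p, which in the scanner files could be followed only for sets with a gene name. Lists of at least 3 measured members were tested with limma's fry and camera (preset correlation 0.01, and estimated). On simulated data for the comparison of stimulated with control fibres, with 15 genes, 3 experiments and 5 genes changed by 0.5 log2, the limma step recovered 61% of the changed genes over 500 repeats. On average 8.6% of its calls were false, above the nominal level.

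The experiment numbers pair stimulated and control RNA by design, since both lie on 1 array. In the scanner channels, deviations of same-numbered stimulated and control extracts from their group means correlated at 0.71, 0.71 and 0.82 across the 24 spot sets. Both extracts were read from the same spots, which alone can make them correlate, so these values do not test the pairing of the extracts. Experiment 3 was scanned on 1 of 2 days and experiments 1 and 2 on the other, so scan day was also fitted as a block. Spots marked by the quantification software, 49 to 81 per array, were kept in the planned fit and left out in an alternative. Alternatives covered the background correction, spot value, normalization, spot summary, spot filters, dye orientation, pairing, array weights, variance trend and each experiment left out. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.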

Results

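Adult flexor digitorum brevis (FDB) fibres, a small mouse foot muscle made mostly of fast fibres, were dissociated from CD-1 mice of 4 to 5 weeks and kept in culture to day 3. Fibres that had received 3 days of electrical stimulation in a slow-twitch pattern were compared with unstimulated fibres of the same day. Stimulated and control RNA were labelled with opposite dyes and hybridised together on a small spotted array that carried 20 named genes, mostly of the contractile apparatus. There were 3 independent experiments, each as a dye swap on 2 arrays, so n = 3. Each array had 144 spots, and the median signal was 1.76 to 4.34 times the local background. The number of arrays limits the precision.

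The comparison asks which muscle genes respond when fast fibres are driven in a slow pattern. The direction of experiment 1 is not settled, because the authors' value table and the scanner files conflict there. Across matched genes, its table column with stimulated RNA in Cy3 ran opposite to its own array (r of -0.89). Its column with stimulated RNA in Cy5 showed little relation to its own array (r of 0.13). The means over the 3 experiments are therefore also given with experiment 1 turned. In the scanner files taken as labelled, no gene passed the threshold, which at n = 3 does not show that none changed. Tnni2, the troponin I of fast fibres, had a mean log2 ratio of stimulated over control of -0.26 ± 0.21 (limma SE, n = 3). Tnnc2, the troponin C of fast fibres, was at 0.21, and Ldhb, the heart-type subunit of lactate dehydrogenase, at 0.21. The limma SE was the same for every matched set, 0.21 as labelled and 0.16 with experiment 1 turned. It reflects a variance shared over sets, not the spread of Tnni2 alone. Tnnc1 stood at -0.11, Tnni1 at -0.09, Mylpf at 0.11, Pvalb at 0.04 and Mb at 0.03. With limma, 0 of 24 spot sets passed an adjusted p of 0.05, the smallest adjusted p was 0.968, and 0 sets had an unadjusted p under 0.05. With experiment 1 turned, Tnni2 was at -0.46 ± 0.16 (adjusted p = 0.0721), Mb at 0.25, Ldhb at 0.25, Tnni1 at 0.19 and Tnnc1 at -0.10, while Mylpf, Tnnc2 and Pvalb were at 0.03, 0.01 and -0.09. Without experiment 1, where 0 of 24 sets passed, Tnni2 was at -0.54 (limma adjusted p = 0.335), Ldhb at 0.34, Mb at 0.21, Tnni1 at 0.08, Tnnc1 at -0.16, Mylpf at 0.10, Tnnc2 at 0.17 and Pvalb at -0.03. In the version with experiment 1 turned, 1 of 24 sets passed, with a log2 ratio of -0.55 and a limma adjusted p of 0.0332. That set could not be matched to a gene. Tnni2 passed in 2 settings with experiment 1 turned, without background correction (-0.48, limma adjusted p = 0.0466) and with the pixel median (-0.49, adjusted p = 0.0376). Its adjusted p was up to 0.977 over the other settings with experiment 1 turned. The gene names of these spots rest on a match to the value table, which placed 8 of the 20 named genes.

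In the authors' value table, read by its column titles, 7 of 15 probe sets passed, 2 of them higher and 5 lower in stimulated fibres, whereas 0 passed with experiment 1 turned. A gene needed at least 3 spots with a value per array, a minimum chosen after the table was seen. Myoglobin (Mb), the oxygen store of oxidative fibres, was 1.39-fold higher, with a log2 ratio of 0.47 ± 0.13 (SD, n = 3) and an adjusted p of 0.0237. Ldhb was 1.40-fold higher at 0.49 ± 0.30 (adjusted p = 0.0257). The calcineurin subunit Ppp3cb, part of the calcium-activated phosphatase, was lower at -0.61 ± 0.055 (adjusted p = 0.0159), as was calmodulin 2 (Calm2), its calcium sensor, at -0.59 ± 0.20 (adjusted p = 0.0162). Myh1, the IIx myosin heavy chain of fast fibres, was lower at -0.58 ± 0.36 (adjusted p = 0.0237), Pvalb, the parvalbumin that buffers calcium in fast fibres, at -0.44 ± 0.10 (adjusted p = 0.0257), and Tnni2 at -0.43 ± 0.24 (adjusted p = 0.0316). Each of these 7 genes had its sign on 6 of 6 arrays. The 2 arrays of an experiment agreed in sign for all 15 probe sets, so this rests on 3 experiments. The same genes with experiment 1 turned were at 0.19 for Mb, 0.27 for Ldhb, -0.19 for Ppp3cb, -0.35 for Calm2, -0.02 for Myh1, -0.07 for Pvalb and -0.16 for Tnni2, all with an adjusted p of 0.892 or more and 0 genes at an unadjusted p under 0.05. Without experiment 1, 0 genes passed and the 2 smallest adjusted p-values were both 0.0964, for Ppp3cb and Calm2, at log2 ratios of -0.60 and -0.70. Mb, Ldhb, Myh1, Pvalb and Tnni2 were then at 0.50, 0.57, -0.45, -0.39 and -0.45. In the scanner files without experiment 1, the called genes with a match were at 0.21 (Mb), 0.34 (Ldhb), -0.03 (Pvalb) and -0.54 (Tnni2). Their signs were the same, but Pvalb was near 0 there, so the sources also differ apart from experiment 1. In the table without experiment 2, 0 genes passed as well, with Ldhb at 0.31, and without experiment 3, 5 of 16. With a minimum of 1 spot, which adds Myh4, 0 of 16 passed, and on the arrays with stimulated RNA in Cy5 alone 0 of 15, while with median centring Pvalb and Tnni2 did not pass (adjusted p = 0.0529 for both). The log2 ratios of the 7 genes were the same with a minimum of 1 spot, and on the arrays with stimulated RNA in Cy5 they lay between -0.63 and -0.39 for the 5 lower genes and at 0.49 for Mb and 0.45 for Ldhb.

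**Figure D1:**
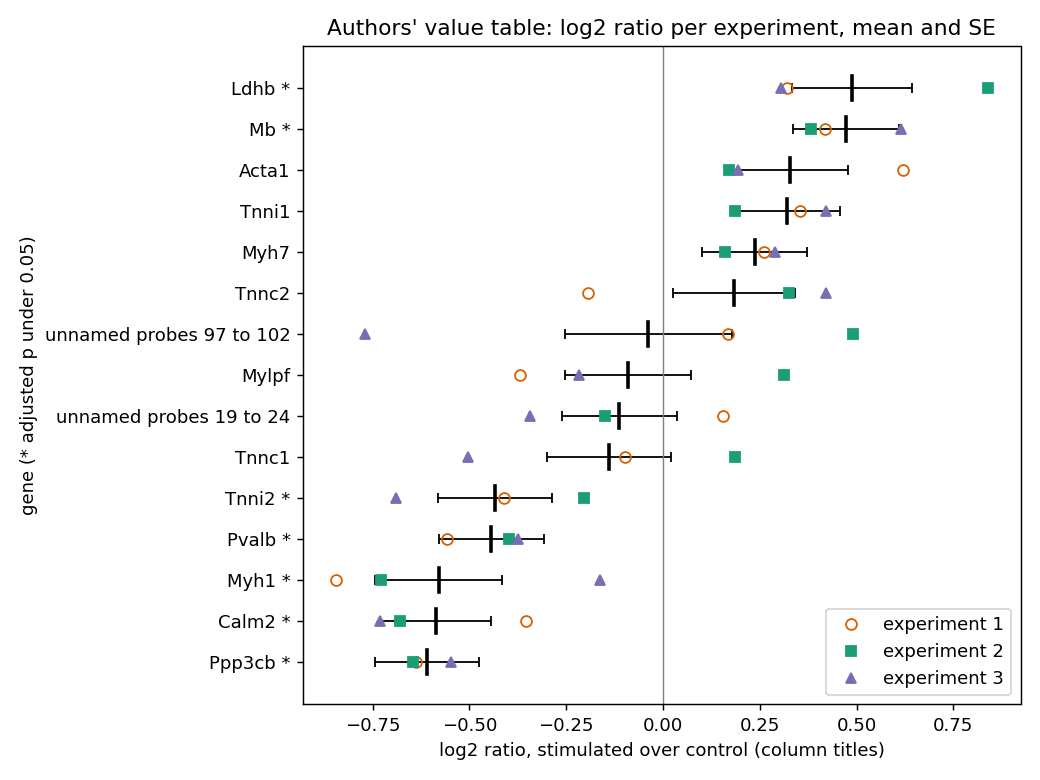
Log2 ratio of stimulated over control in the authors' value table (horizontal axis) for 15 probe sets (vertical axis), with direction taken from the column titles. Points are the 3 experiments, each the mean of 2 dye-swapped arrays, with experiment 1 open because its direction is not settled; black lines are the mean and the limma SE, and stars mark the 7 genes with an adjusted p under 0.05, from Ppp3cb at -0.61 to Ldhb at 0.49.

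Genes of the slow contractile list did not pass in the value table. Tnni1, the slow troponin I, was at 0.32 ± 0.12 (SD, n = 3, limma adjusted p = 0.0779) and Myh7, the slow myosin heavy chain, at 0.24 ± 0.068 (adjusted p = 0.164), both positive on 6 of 6 arrays as the titles read, and at 0.08 and 0.06 with experiment 1 turned. Tnnc1, the troponin C shared by slow and cardiac muscle, was at -0.14 ± 0.35 (adjusted p = 0.509) and at -0.07 turned, so 0 of 3 members passed over all genes and 0 adjusted over the list alone. Of the fast contractile list, 3 of 5 members fell as the titles read, Myh1, Pvalb and Tnni2, and 3 also passed adjusted over the list alone. Tnnc2 at 0.18 ± 0.33 and Mylpf, the fast regulatory light chain, at -0.09 ± 0.36 did not pass. With experiment 1 turned they were at 0.31 and 0.16, and without experiment 1 at 0.37 and 0.049. Without experiment 3 Tnnc2 was at 0.065. As sets, neither list stood apart from the other genes. The slow list had a mean log2 ratio of 0.14 and the fast list of -0.27, with an adjusted p of 0.293 for both from limma's camera and of 0.384 for both with an estimated correlation. With limma's fry, which asks only whether a list moves one way, the adjusted p was 0.0546 for the slow list and 0.12 for the fast list. For a change of members in either direction, fry gave unadjusted p-values in limma of 0.0818 and 0.0122. With experiment 1 turned the list means were 0.02 and 0.04, fry's adjusted p in limma was 0.857 for both, and its p for either direction was 0.869 and 0.824. Without experiment 1 the list means were 0.12 and -0.17. In the scanner files as labelled the 2 slow members with a match averaged -0.10 and the 4 fast members 0.03 (camera in limma, adjusted p = 0.931, and 0.953 with an estimated correlation), and with experiment 1 turned 0.05 and -0.13.

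The other lists had few genes on the array. Both members of the calcium and activity-dependent signalling list, Ppp3cb and Calm2, fell as the titles read, with 2 of 2 passing adjusted over the list alone. Mb was the only member for oxidative metabolism and Ldhb the only one for glycolysis, and each passed over all genes and adjusted over the list alone. Acta1, the skeletal actin and only member for the sarcomere, was at 0.33 ± 0.25 (SD, n = 3, limma adjusted p = 0.0856). It was at -0.08 with experiment 1 turned and at 0.18 without experiment 1. Csrp3, the only myogenic regulator, had no value in the table. The lists for developmental isoforms, calcium handling, growth and atrophy, and stress, and all 7 lists of other cell types, had no named gene on the array, so the cell content of the cultures was not measured. The 2 probe sets without a name were at -0.11 ± 0.25 and -0.04 ± 0.65, and at -0.22 and -0.15 with experiment 1 turned.

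In the value table with at least 3 spots per gene, Pearson's r across genes, which are not independent replicates, was 0.89 to 0.92 within a dye swap and 0.44 to 0.78 between experiments. With at least 1 spot these ranges overlapped, at 0.55 to 0.78 and 0.25 to 0.85. With at least 3 spots, experiments 2 and 3 correlated with each other at 0.46 to 0.54. In the scanner files as labelled, r across the 24 spot sets was 0.64 to 0.73 within a dye swap. Arrays of experiment 1 correlated with those of experiments 2 and 3 at -0.58 to -0.004, and experiments 2 and 3 with each other at -0.006 to 0.28. Among arrays of the same dye orientation, experiment 1 had an r of -0.51 with experiment 2 and -0.30 with experiment 3 where stimulated RNA was in Cy5, and of -0.004 and -0.15 where it was in Cy3. To compare the table with the scanner files, spots were matched to genes from 1 experiment and the ratios were then compared in another. Each such match accepted 8 probe sets, 6 of them placed as in the match from both experiments. Matched from experiment 2, the columns of experiment 3 had r of 0.70 and 0.89 with their own arrays across gene means. Matched from experiment 3, the columns of experiment 2 had r of 0.90 and 0.87 with theirs, and of -0.94 and -0.99 with the other array of the swap, where a dye swap gives a negative value. Over spots within genes they followed the other array more closely, at -0.81 and -0.31, against 0.58 and a value near 0 with their own. Experiment 1 had no part in any match. Its column with stimulated RNA in Cy3 had an r of -0.89 with its own array over the 10 sets matched from both experiments, and of -0.96 and -0.93 when matched from experiment 2 or 3 alone. Its column with stimulated RNA in Cy5 had r of only 0.13, -0.30 and -0.06 with its own array. With the array carrying stimulated RNA in Cy3, where a dye swap gives a negative value, that column had r of 0.97, 0.77 and 0.99. The column with stimulated RNA in Cy3 had r of -0.17, 0.83 and 0.05 with the array carrying stimulated RNA in Cy5. Neither source states which of the records holds for experiment 1.

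**Figure D2:**
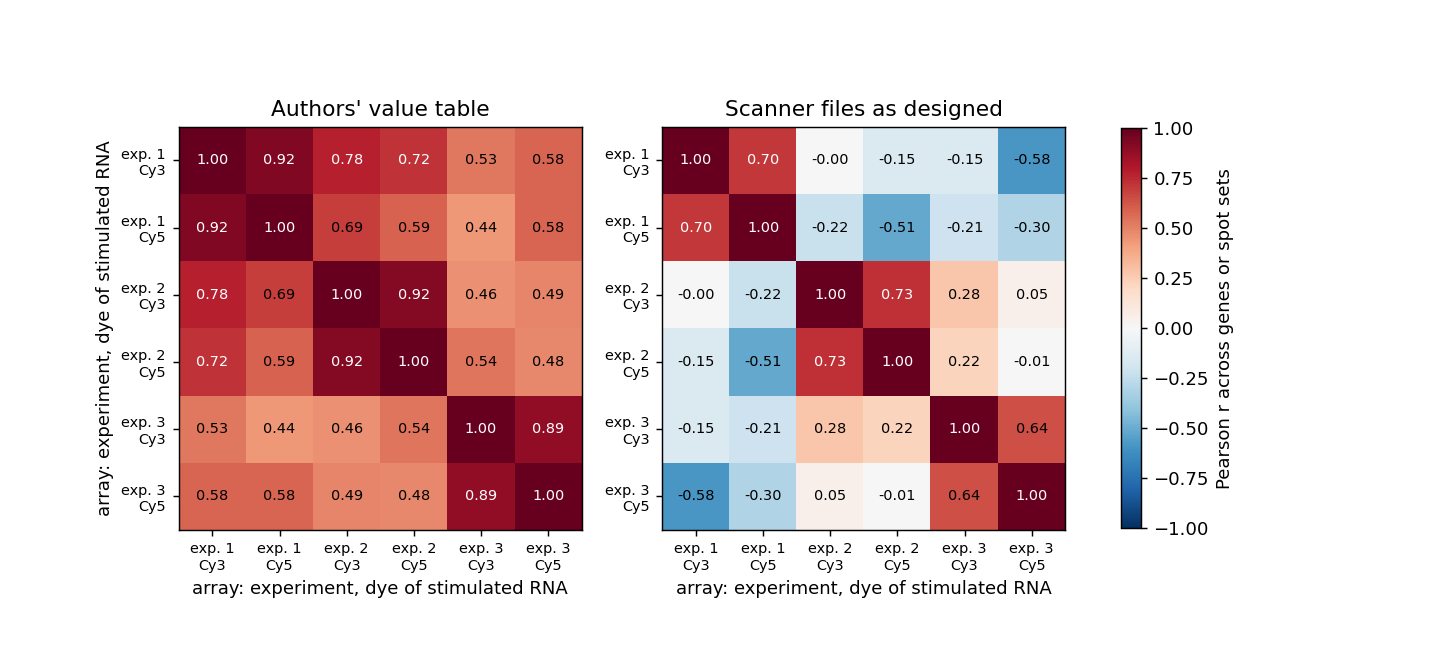
Pearson's r of the log2 ratio stimulated over control between the 6 arrays (both axes, named by experiment and by the dye of the stimulated RNA), across 15 probe sets of the value table on the left and 24 spot sets of the scanner files as labelled on the right. In the table every pair is positive, from 0.44 to 0.92, whereas in the scanner files the arrays of experiment 1 stand between -0.58 and -0.004 against the other experiments.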

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

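Chosen after seeing the data were all settings with experiment 1 turned, scan day as a block, and all settings within the value table. The cause was not tested for any change below unless stated. With the scanner files as labelled, all 20 settings gave 0 sets past the threshold. They include those with the experiment as a random replicate block and with no replicate block (0 each), and the 3 that leave out an experiment (0 to 0). With experiment 1 turned, 11 of 20 settings gave 0 sets. The count was 1 as designed, without background correction, with normexp offset 10, with median centring, with the median of the spots and with array weights, and 2 with the pixel median and without normalization. It was 0 to 2 when an experiment was left out. The value table, whose use was planned, gave 7 with a minimum of 3 spots that was chosen after the table was seen.

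Within the value table, the count was 7 with the median of the spots, the mean of the linear ratios, array weights, scan day as a block, and the experiment as a random replicate block with a dye term, and the same 7 genes passed in each. It was 6 on the arrays with stimulated RNA in Cy3 only and 5 with median centring, where Pvalb and Tnni2 had an adjusted p of 0.0529 and 40.0% of the calls were higher against 28.6%. It was 0 on the arrays with stimulated RNA in Cy5 only, 0 with experiment 1 turned, 0 with at least 1 spot per array (9 genes at an unadjusted p under 0.05) and 4 with at least 5 spots, where 10 genes were tested. Leaving out an experiment gave 0 to 5, from fewer values per gene. Within the scan day that held experiments 1 and 2, 5 passed, and the other day held 1 experiment.

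In the scanner files the slow list mean of -0.10 turned to 0.034 without normalization, 0.047 with experiment 1 turned, 0.139 in the value table and 0.025 in the value table with experiment 1 turned. It was -0.018 with median centring, and leaving out an experiment gave -0.152 to -0.040. The fast list mean of 0.03 turned to -0.037 on the arrays with stimulated RNA in Cy5 only, -0.021 with scan day as a block, -0.129 with experiment 1 turned and -0.273 in the value table. It was 0.125 without the spots the software marked, and leaving out an experiment gave -0.076 to 0.125. In the value table the fast list mean of -0.27 turned to 0.044 with experiment 1 turned, and was -0.540 with at least 1 spot, where Myh4 joins at -1.88. Leaving out an experiment gave -0.340 to -0.171 for it and 0.121 to 0.175 for the slow list. With scan day as a block the table's list means were 0.12 (slow) and -0.26 (fast), and within the day of experiments 1 and 2 they were 0.17 and -0.31.

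The mean r of dye-swapped arrays, 0.692 as designed, was 0.912 in the value table, also with experiment 1 turned, 0.642 without background correction, 0.607 with plain subtraction, 0.757 with median centring or without normalization, and 0.637 with the median of the spots. In the value table with at least 1 spot it was 0.70, and 0.559 between experiments. Between experiments the mean r was -0.132 as designed, 0.573 in the value table, -0.246 in the value table with experiment 1 turned, 0.222 in the scanner files with experiment 1 turned, and 0.068 with plain subtraction.

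The 7 called genes lost the call in 40 of their 95 values under other settings in the table, with no change of sign. Of all 205 gene values, 8 turned. Acta1 was -0.085 and Mylpf 0.155 with experiment 1 turned, while leaving out an experiment gave Mylpf -0.292 to 0.049, Tnnc1 -0.301 to 0.044 and the unnamed probe sets -0.247 to 0.003 and -0.301 to 0.329. The latter was 0.002 on the Cy3 arrays only and 0.009 with array weights. Subgrid loess was not run since the array has 1 subgrid, nor centring on housekeeping genes, since none of the 20 named genes is one. Signal at 1.76 to 4.34 times background limits the dimmer genes, and 15 of 22 probe sets had enough values to test.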

Other observations

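Some genes on the array had table values in too few arrays for the comparison, and are given as values. Mgp, the matrix Gla protein, an inhibitor of calcification, had log2 ratios of stimulated over control of 0.82 and 1.01 on the 2 arrays of experiment 3 and too few spots elsewhere. Ppp2ca, a catalytic subunit of protein phosphatase 2A, averaged 0.015 over experiments 1 and 2 and was at 0.82 on 1 array of experiment 3. Myh4, the IIb myosin heavy chain, was at -2.05 on 1 array of experiment 2. Myh6, Pln, Csrp3 and CAMTA1 had enough spots on no array. These genes were singled out after their values were seen.

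All tests below were chosen after the results were seen. In experiment 1 the value table and the scanner files conflict, most clearly for the column with stimulated RNA in Cy3. Measurement noise particular to each array of experiment 1 would leave its dye-swapped arrays unrelated. They had an r across genes of 0.704 in the scanner files and 0.924 in the table, unlike such noise alone. Error common to both arrays, which were taken as the same RNA extracts, would also give a high r and was not tested. The tests of experiment 1 were redefined more than once after their values were seen. The verdict on noise changed each time, so these values are descriptive. An exchange of the records of the 2 arrays, which predicts that each column follows the other array's files over spots within genes, stays open. That r was 0.78 for the column with stimulated RNA in Cy5, with 0.21 and 0.72 when spots were matched from experiment 2 or 3 alone. It was 0.25, 0.20 and 0.12 for the column with stimulated RNA in Cy3, where low values decide nothing. A column of experiment 3, matched from experiment 2, had an r of only 0.27 with its own array. A column of experiment 2 was near 0 with its own array too, but followed the other array more closely, at -0.31, so it is no clean reference. An opposite response of the fibres of experiment 1 would show alike in both records of the same hybridisations. It could therefore not make the records differ, whatever the values. The mean r of experiment 1 with the other experiments, 0.614 in the table and -0.265 in the scanner files, only restates the conflict. Whether these fibres responded in the opposite direction was not tested, and the direction they took depends on the record used.

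By the titles of the value table, 7 of 15 genes passed the threshold. Dye bias left after averaging the swapped arrays would give opposite signs on the arrays of a swap, but all 7 called genes kept 1 sign on both arrays in each of the 3 experiments, as did all 15 genes tested. The equal signs thus do not set the called genes apart. For experiment 1 they cannot decide. Across matched genes both of its table columns tracked the scan of the array with stimulated RNA in Cy3, with r of -0.89 and 0.97. They were therefore not shown to be separate readings. Turning the sign of each experiment makes 4 splits, too few for a share under 0.05: the real value was 7 genes and the highest of the others 0, with 1 of the 4 splits as large. In the scanner files as labelled the real value was 0 sets and the highest of the others 1. With a real value of 0, all 4 of the 4 splits are as large by construction, so that count says nothing. A biological effect of stimulation stays among the open explanations.

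Ppp3cb and Calm2 had the smallest adjusted p-values of the value table, with 3 spots on each array of experiment 1 and 4 to 6 on the others. Neither gene was matched to scanner spots, so whether the scanner files hold the same direction for them was not tested.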
